A study of Mus musculus with 4 samples.

How the data were processed

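The data were single-cell RNA libraries (10x 3' chemistry) of liver cells enriched for non-parenchymal cells and macrophages, 1 library for each of 4 groups: genotype A/A or S/S, at baseline or 3 h after 500 ng TNF given intraperitoneally. Cells of 2 mice were pooled per library, so there were no replicates. Per the labels and file headers, the authors made UMI counts per gene and barcode with Cell Ranger against mm39, and the deposited matrices held these integer counts. The headers named version 6.1.2 for both TNF libraries and 7.1.0 for both baseline libraries. Whether introns were counted is not stated, and version and treatment cannot be separated. The TNF matrices held no barcode under 250 genes or over 20% mitochondrial UMIs, while the baseline matrices did. Each matrix had 55414 genes. Genes were matched by identifier and, for the lists, by symbol; 627 of 629 listed genes were found. No coordinates were used. Intron lengths came from a reference annotation of an earlier build (GRCm38) by gene identifier and served as a property of the gene alone, available for 99.97, 99.96, 99.95 and 99.97% of the genes compared in Kupffer-like cells.

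Barcodes with at least 300 genes and at most 20% mitochondrial UMIs were kept. Scrublet was run per library at an expected rate of 0.8% per 1000 barcodes. It called 6, 0, 2 and 0 doublets where 64, 152, 333 and 244 would be expected, so doublet removal did not work. Some clusters with mixed markers stayed unnamed by the rule below. Others were named, such as cluster 24 (NK or ILC1-like) with 9 NK or ILC1 and 9 T cell markers. Kept cells numbered 2824, 4366, 6450 and 5528, with 20435597, 29710749, 53439431 and 53969689 UMIs in total. Counts were scaled to 10000 per cell and logged. Of the genes, 2000 variable ones were picked per library and combined, without mitochondrial, ribosomal protein and sex-linked genes and without listed genes other than markers. They were scaled, limited to 10 SD, and reduced to 30 principal components, and a shared-neighbour graph of 15 neighbours was clustered by the Leiden method at resolution 1. A cluster took the class with the largest share of its markers higher by a log2 ratio of at least 1 (prior 10 CPM) and seen in at least 10% of its cells; 3 markers were needed. Clusters stayed unnamed when another class had more markers among the 10 leading genes, when 5 of those were mitochondrial, or when depth was under 1 part in 3 of the library median with no own marker among them. No correction between libraries was made. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.

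For each class with at least 50 cells in each library compared, UMIs were summed per library and scaled to the library total of the class (CPM), and log2 ratios used a pseudocount of 1 CPM. Comparisons were TNF against baseline within A/A and within S/S, S/S against A/A at baseline and after TNF, and the difference between the TNF ratios. Intervals are exact binomial 95% intervals, which cover counting error only and leave out the differences between mice and preparations, and no test was made from cells. A gene entered a list or a correlation with at least 20 UMIs in the pair, or at least 100 over the 4 libraries for correlations. A fold against 0 UMIs is given as a lower bound against a floor of 3 UMIs. In Kupffer-like cells the median log2 ratio of all compared genes was 0.14, 0.23, -0.11 and -0.074 in the 4 comparisons in the order given. Members at 0 UMIs were found behind 9 of 82 list medians, and placing them at their bound lowered 2 of these, by 0.53 and 0.058, and left the others as they were. Genes with shared symbols or near-identical copies are uncertain.

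Genes were named by a rule of size. In Kupffer-like cells, genes with at least 100 UMIs in the pair and at least 20 CPM in the higher library, and no lower in the class than in the other cells of that library, gave the 10 highest and 10 lowest ratios of each comparison. Across the comparisons of 1 factor, 10 genes each way were taken by the smaller of the ratios of the same sign, for the difference between TNF ratios 5 each way, in other classes 3 each way, and in each list up to 4 members with the largest absolute ratio, ties going by symbol. Lists were NF-kB and TNF response, interferon-stimulated genes, heme and iron handling, NRF2 and oxidative stress, MHC class II presentation, MHC class I presentation, scavenger receptors and efferocytosis, complement, lipid-associated macrophage genes, inflammasome and cell death, adhesion and coagulation, cytokine and growth factor ligands, chemokines, glycolysis, cholesterol synthesis and uptake, cell cycle, dissociation stress, unfolded protein response, hepatocyte acute phase, mitochondrial transcripts and sex-linked transcripts. Each list has a median, a counting interval from 1000 resamples and a percentile among 10000 random lists of like expression. Groups, comparisons, lists, markers, the naming rule and the first set of alternatives were fixed before the data were examined.

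The procedure was tested on simulated data, drawn from the 2 libraries of each comparison with 200 genes set to differ. Intervals held the true ratio for 96.3, 96.1, 95.96 and 96.1% of 4796, 4134, 3963 and 5637 genes, and 5, 4.5, 6 and 6.5% of 200 random lists of 40 genes fell outside the middle 95%. Genes set higher and lower had median log2 ratios of 0.93 and -0.98 (2-fold), 2.06 and -2.04 (4-fold), 2.98 and -2.87 (8-fold) for TNF in A/A, 0.82 and -1.16 (2-fold), 1.82 and -2.12 (4-fold), 2.85 and -3.03 (8-fold) for TNF in S/S, 0.82 and -1.22 (2-fold), 1.67 and -2.14 (4-fold), 2.69 and -3.14 (8-fold) for genotype at baseline, and 0.98 and -1.04 (2-fold), 1.94 and -1.99 (4-fold), 3.01 and -2.95 (8-fold) for genotype after TNF. Alternatives altered 1 setting at a time, except that the filter altered both limits and thinning also left out shallower cells: at least 500 genes and 10% mitochondrial UMIs per cell, doublets kept, listed genes among the variable genes, Leiden resolution 2, cells thinned to 1000 UMIs, the mean of each cell's CPM, median-of-ratios size factors, a minimum of 1 UMI, a pseudocount of 10 CPM, genes more abundant in other cells left out of the lists, and 500 UMIs for correlations. Chosen after the data were seen were removal of the highest doublet scores at the expected rate, totals without ribosomal RNA, cluster 4 alone, barcodes with a UMI of Clec4f, Timd4 or Vsig4 alone, list genes with under 10 kb of intron, and Ftl1 summed with its pseudogenes. Raw reads were not used here, and RNA from other cells in the droplets was measured against the other cells of each library but not subtracted.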

Results

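Single-cell RNA expression was measured in cells isolated from the livers of 2-month-old mice of the genotypes A/A and S/S, either untreated (baseline) or 3 h after an intraperitoneal dose of 500 ng of the inflammatory cytokine TNF. The labels do not spell out what the genotype symbols A and S stand for. Each of the 4 groups (A/A baseline, S/S baseline, A/A TNF and S/S TNF, the order kept for all lists of 4 values) held 1 library. Each was made from the pooled cells of 2 mice after low-speed spins, a density gradient and a flow sort that enriched macrophages and live cells. There were no replicates, so no comparison was tested. All intervals, given in brackets, are 95% intervals for counting error only. The libraries held 3230, 4983, 6531 and 5848 barcodes with 21088801, 30724027, 53556431 and 54999906 UMIs (unique transcript molecules). After filtering, 2824, 4366, 6450 and 5528 cells remained, with a median of 4708.5, 5507, 5864.5 and 6504.5 UMIs and 1511, 1917.5, 1500 and 1401.5 genes per cell. Both TNF libraries had been processed with another version of the counting software than both baseline libraries, so every TNF comparison also compares the versions. Ribosomal RNA transcripts of Rn18s-rs5 took 16.7, 6.19, 14.3 and 13.9% of all UMIs.

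Clustering gave 41 clusters, of which 9 stayed unnamed, and cell classes were named anew from marker genes, so all names carry the ending "-like". Neutrophil-like cells made up 21.8% [20.8 to 22.8] of the kept cells of the A/A TNF library and 20.4% [19.3 to 21.4] of the S/S TNF library, against 4.82% [4.06 to 5.67] and 3.64% [3.11 to 4.24] in the A/A and S/S baseline libraries. Lymphocytes had lower shares in the TNF libraries: B cell-like cells took 15.3, 21.6, 3.55 and 2.88%, T cell-like cells 16.6, 19.97, 13.9 and 5.54%, and NK or ILC1-like cells 4.96, 7.03, 3.77 and 1.86%. Kupffer-like cells, the resident macrophages of the liver sinusoids, made up 14.3% [13.1 to 15.7], 12.02% [11.1 to 13.03], 8.70% [8.02 to 9.41] and 7.60% [6.91 to 8.33], which is 405, 525, 561 and 420 cells. Erythroid-like cells set the genotypes apart at both times, with 7.38% [6.62 to 8.19] and 12.3% [11.4 to 13.2] in the S/S baseline and TNF libraries against 0.496% [0.271 to 0.830] and 0.698% [0.509 to 0.932] in the A/A ones. Monocyte or macrophage-like cells took 3.29, 6.55, 5.38 and 9.37%, mature DC-like (dendritic) cells 2.12, 1.21, 2.57 and 5.19%, and pDC-like (plasmacytoid dendritic) cells 6.41, 5.36, 3.23 and 2.88%. Hepatocyte-like barcodes took 16.8, 6.94, 7.02 and 8.16%, endothelial-like cells 11.97, 0.825, 5.77 and 5.32%, plasma cell-like cells 0.567, 0.710, 1.08 and 0.525%, and unnamed clusters 1.91, 6.55, 22.03 and 17.5%. Some shares moved with the clustering. Unnamed cluster 1, with 14 endothelial markers, held 4, 11, 1168 and 447 cells. Endothelial-like cells took 12.08, 1.08, 23.9 and 13.4% with predicted doublets kept and 12.08, 0.825, 16.3 and 6.11% at Leiden resolution 2. With listed genes left among the variable genes, neutrophil-like cells took 4.78, 3.48, 10.65 and 8.29%, unnamed clusters 1.20, 4.03, 31.3 and 26.1%, and NK or ILC1-like cells 4.92, 7.54, 5.43 and 2.66%, the last no longer lower after TNF in A/A. Mature DC-like cells took 0.921, 0.344, 2.56 and 5.10% in that setting and 0.496, 0.1603, 1.54 and 3.42% at Leiden resolution 2. With at least 500 genes and at most 10% mitochondrial UMIs per cell, erythroid-like cells took 0.213, 3.70, 0.371 and 5.25%, Kupffer-like cells 14.3, 8.04, 6.79 and 5.86%, monocyte or macrophage-like cells 2.72, 7.89, 7.12 and 15.7%, and hepatocyte-like barcodes 11.8, 4.02, 5.325 and 4.70%, the last no longer higher in S/S than in A/A after TNF. Kupffer-like cells took 11.6, 6.12, 8.22 and 5.499% at Leiden resolution 2, so the size of the baseline gap between the genotypes depended on these choices. Monocyte or macrophage-like cells took 3.895, 8.68, 6.19 and 12.4% with listed genes left in. These shares also depend on the sort, on the depth of each library and on the filter on genes per barcode already present in the TNF matrices. Most classes were held by different clusters at baseline and after TNF.

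**Figure D1:**
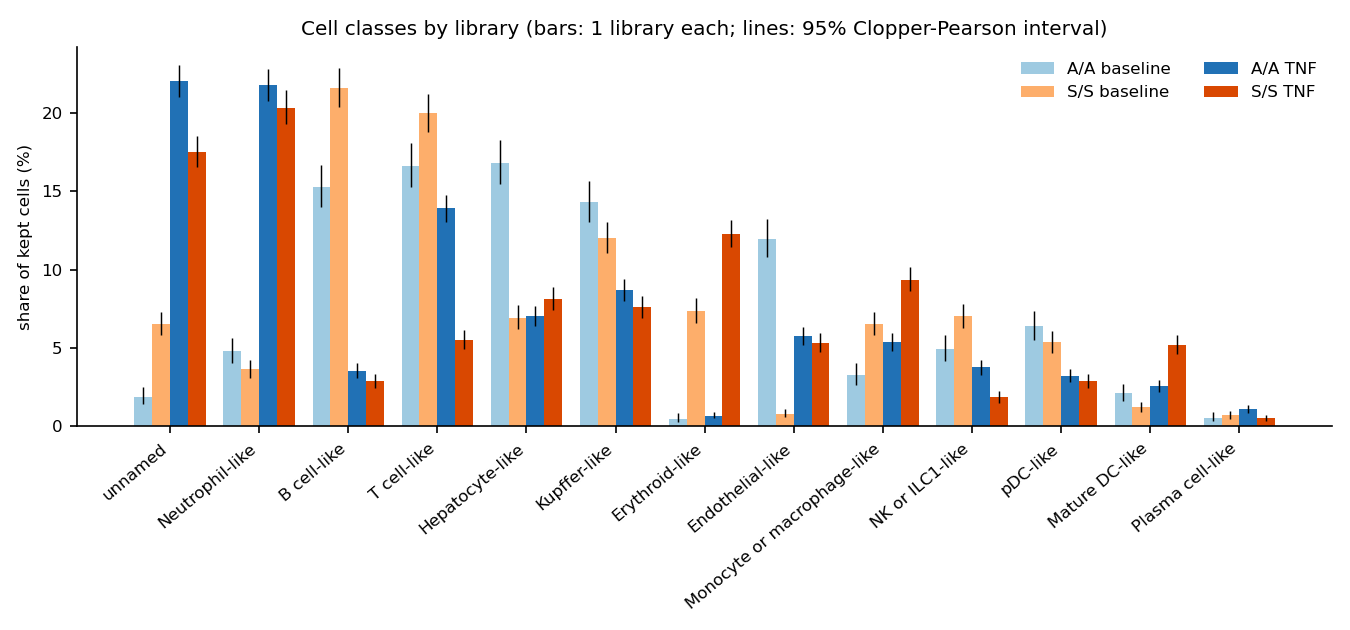
Share of kept cells (%) in each rebuilt cell class, with 1 bar per library and lines for the exact binomial (Clopper-Pearson) 95% interval, which covers counting error only. Neutrophil-like cells stood at 21.8% and 20.4% in the TNF libraries, and erythroid-like cells at 7.38% and 12.3% in the S/S libraries.

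The series set out to separate the effects of genotype and of TNF on liver cells, and the first question was how Kupffer-like cells of A/A mice differed 3 h after TNF. Genes of the NF-kB pathway, the main transcriptional route downstream of the TNF receptors, were higher in the A/A TNF library than in the A/A baseline library. In this pair 37 of 38 measured list members were higher and 31 were over 2-fold higher. Sdc4 (ENSMUSG00000017009.4), a cell-surface heparan sulfate proteoglycan, was 42.7-fold higher, at 1004 against 22.5 CPM (counts scaled to the class total of each library), and Cxcl13 (ENSMUSG00000023078.7), a B cell-attracting chemokine, 21.7-fold higher. The metallothioneins Mt2 (ENSMUSG00000031762.8) and Mt1 (ENSMUSG00000031765.9), which bind zinc, were 174-fold and 24.4-fold higher, and Akap12 (ENSMUSG00000038587.11), a scaffold protein, went from 4 to 1066 UMIs, a log2 ratio of 7.04 [6.003 to 9.24]. Akap12 also led unnamed cluster 1 (3362 CPM), which had 14 endothelial markers and held 4 and 1168 cells in A/A at baseline and after TNF. RNA of those cells in Kupffer-like barcodes was not excluded. In contrast, the interferon-stimulated genes Ifi27l2a (ENSMUSG00000079017.4), at 1824 CPM at baseline and 43.00 CPM after TNF, and Irf7 (ENSMUSG00000025498.16), a transcription factor of the interferon response, were lower, with log2 ratios of -5.37 and -3.48.

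Other genes named by size in A/A were Gpr84, a receptor for medium-chain fatty acids (log2 ratio 4.64 [3.66 to 6.54]), Marcksl1, an actin regulator (3.96 [3.79 to 4.14]), Gbp5, an interferon-inducible GTPase (3.74 [3.24 to 4.39]), Ell2, an elongation factor (3.68 [2.94 to 4.82]), and Txnrd1, a thioredoxin reductase (3.35 [3.04 to 3.71]). Pancreatic digestive enzymes, among them Clps and Ctrb1, also stood among the highest genes (at least 229-fold and at least 131-fold against a floor of 3 UMIs), with 99.7% and 99.7% of their UMIs in 1 barcode. The genes lowest in the A/A TNF library were Cmss1 (-12.10), Cdk8 (-9.26), Gphn (-7.73) and Camk1d (-7.02), together with Il31ra (at least 1149-fold lower), with annotated introns of 302868, 61813, 454645, 413632 and 68790 bp. Cmss1 was also among the 3 lowest genes of B cell-like, T cell-like, NK or ILC1-like, mature DC-like and hepatocyte-like cells in both genotypes. Kupffer-like cells of A/A came mostly from cluster 22 at baseline (262 of 405 cells) and from cluster 15 after TNF (367 of 561), and their median depth was 2129 and 2239 UMIs.

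In S/S Kupffer-like cells the same question gave an NF-kB list with 37 of 38 members higher and 36 over 2-fold higher in the TNF library. Sdc4 was 51.8-fold higher, at 1212 against 22.4 CPM, and Cxcl2 (ENSMUSG00000058427.11), a neutrophil-attracting chemokine, 86.7-fold higher. Tnfaip3 (ENSMUSG00000019850.12), the NF-kB inhibitor A20, was 27.05-fold higher. Cxcl13 (4.76 [3.75 to 6.62]), Marcksl1 (4.70 [4.40 to 5.04]), Gbp5 (4.38 [3.57 to 5.65]) and Mt1 (4.17 [3.97 to 4.39]) were higher in S/S as in A/A, and Gpr84 was at least 27.9-fold higher. Ifi27l2a (-4.40 [-4.63 to -4.19]), Irf7 (-3.37 [-3.91 to -2.95]) and Cd72, an inhibitory receptor (-3.45 [-4.29 to -2.86]), were lower in the S/S TNF library.

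Further genes named by size in S/S were Gdf15 (ENSMUSG00000038508.8), a stress-induced cytokine (4.51 [3.56 to 6.16], with 33.3% of its UMIs after TNF in 1 barcode), Clic4, an intracellular chloride channel (3.97 [3.41 to 4.71]), Jdp2, a repressor of AP-1 (3.96 [3.42 to 4.66]), and Serpina1e, a protease inhibitor made by hepatocytes (at least 23.5-fold higher). Lowest beside Cmss1 (-10.20), Cdk8 (-7.998) and Gphn (-6.74) was Cd209f, a C-type lectin (-5.98 [-7.43 to -5.21]), and its neighbour Cd209g was lower with 3 UMIs left after TNF (-5.71 [-8.53 to -4.66]). Most S/S Kupffer-like cells lay in cluster 4 at both times (466 of 525 and 292 of 420), at a median depth of 1362 and 1715.5 UMIs. Across 4634 genes, which are not independent replicates, the A/A and S/S log2 ratios had a Pearson correlation of 0.71 and a Spearman correlation of 0.71, and 76.7% of the genes had the same sign. Both comparisons hold the same difference in software version, which can raise these values.

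**Figure D2:**
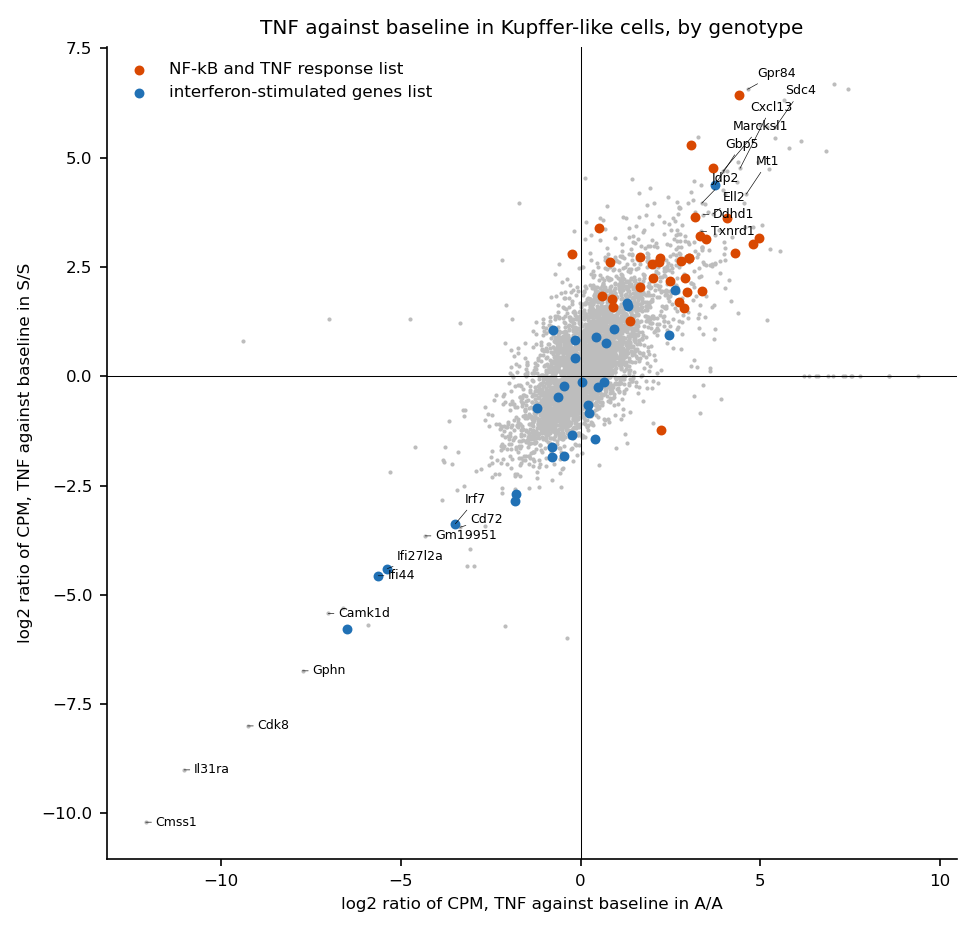
Log2 ratio of CPM for TNF against baseline in A/A (x axis) and in S/S (y axis), with 1 point per gene in Kupffer-like cells and genes of the NF-kB and interferon lists in colour. NF-kB genes lay in the upper right (medians 2.51 and 2.67), and interferon-stimulated genes such as Ifi27l2a in the lower left (-5.37 and -4.40).

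Lists of genes fixed in advance described the TNF comparisons by function, each by its median log2 ratio and by the percentile of that median among random lists of like expression. The NF-kB and TNF response list had medians of 2.51 [2.22 to 2.77] in A/A and 2.67 [2.42 to 2.78] in S/S, at percentiles 100 and 100. In A/A, Ccl2, a monocyte-attracting chemokine, was at 4.29, and Tnf itself had 2 UMIs at baseline and 135 after TNF (4.81 [3.502 to 8.44]). Il6, an inducer of the acute phase, and Cxcl1 had no UMI in S/S at baseline and were at least 11.4-fold and at least 12.7-fold higher. Chemokines had medians of 2.45 and 0.94, with 11 and 9 of 19 measured genes over 2-fold higher. Cxcl14, however, was lower in A/A (-4.61) and Ccl8 lower in S/S (-4.06 [-10.61 to -2.64], from 25 UMIs to 1). Cytokine and growth factor ligands stood at 1.88 and 2.43, with 10 and 11 of 16 over 2-fold higher. Il12b, a subunit of interleukin 12, was at least 8.04-fold and at least 11.4-fold higher, and Il10 at least 4.95-fold higher in A/A. Adhesion and coagulation genes had medians of 1.29 and 1.01, with the leukocyte ligands Icam1 at 4.07 and 3.62 and Vcam1 at 3.19 and 3.65. Inflammasome and cell death genes had medians of 0.43 and 0.76, with 8 and 11 of 24 over 2-fold higher, among them the death receptor Fas (4.78 [3.48 to 8.42] and 3.42 [2.27 to 5.59], with 2 UMIs in A/A at baseline) and the sensor Nlrp3 (2.74 and 3.85).

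Interferon-stimulated genes were lower on balance, with medians of -0.34 [-0.51 to -0.11] in A/A and -0.56 [-0.82 to -0.36] in S/S at percentiles 0.330 and 0, and with 13 of 40 and 18 of 42 members over 2-fold lower. Members went both ways: Gbp5 was higher (3.74 and 4.38) while Ifi27l2a, Irf7 and Ifi44 were lower (Ifi44 -5.63 and -4.56, with 5 UMIs in S/S after TNF). Cell cycle genes were lower, with medians of -1.06 and -1.15 and 7 of 13 and 8 of 15 over 2-fold lower, such as the replication helicase subunit Mcm5 in A/A (-2.96) and the thymidylate synthase Tyms in S/S (-1.95). MHC class II presentation genes had medians of -0.031 and -0.44, with their regulator Ciita at -1.23 in A/A and H2-Eb1 at -1.23 in S/S against Cd40 at 2.65 and 2.91. MHC class I presentation genes had medians of 0.74 and 0.43, with 6 of 18 and 6 of 17 over 2-fold higher. With cluster 4 alone the A/A median of that list was -0.12.

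Oxidative stress genes of the NRF2 list had medians of 0.995 [0.80 to 1.33] and 1.34 [1.07 to 1.55], with 12 and 15 of 24 over 2-fold higher and none over 2-fold lower. After metallothionein it was led by Txnrd1 (3.35 and 3.32) and the cystine transporter Slc7a11 (3.18 [1.52 to 9.47] and 3.76 [2.52 to 6.42], with 1 and 3 UMIs at baseline). Heme and iron handling genes stood at 0.65 and 0.59, with 12 of 28 and 10 of 27 over 2-fold higher. Hmox1, the heme-degrading enzyme, had ratios of 3.13 [3.04 to 3.23] and 1.75 [1.68 to 1.82]. Scavenger receptors and efferocytosis genes had a median of 0.27 in A/A and 1.38 in S/S, with 7 of 21 and 12 of 20 over 2-fold higher, such as Msr1 (2.40 and 2.12) and in S/S the efferocytosis receptor Mertk (2.06). Complement genes had medians of 0.26 and 0.22, with the anaphylatoxin receptor C5ar1 at 3.75 and 2.60, and lipid-associated macrophage genes 0.26 and 0.01, with Fabp4 at 3.37 and 2.96 and Trem2 lower in A/A (-1.71). Fabp4 was also a leading gene of unnamed cluster 1 with its endothelial markers, so RNA of those cells was not excluded. Cholesterol synthesis and uptake stood at 0.64 and 1.14, with Srebf2, an activator of sterol synthesis, at 1.30 and 1.75 (S/S -0.35 in cells thinned to equal depth). Glycolysis stood at 0.24 and 0.73 (S/S -0.034 without genes more abundant in other cells), with the glucose transporter Slc2a1 at 2.68 and 2.67.

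Unfolded protein response genes had medians near 0 (0.005 and -0.15), with Atf4 higher (2.31 and 2.48) and Sdf2l1 lower (-2.45 and -1.98). Dissociation stress genes, which cell isolation itself can induce, had medians of 0.23 in A/A and 1.04 in S/S, where Dusp1 was at 3.58. Mitochondrial transcripts were higher, with medians of 1.57 and 0.86, and the median mitochondrial share per Kupffer-like cell was 2.11, 4.25, 5.94 and 4.95%. Acute phase proteins of hepatocytes had medians of 3.39 and 1.87 in Kupffer-like cells (2.87 in A/A with a member at 0 UMIs set at its bound). Saa1, for example, was at 79.95 CPM in this class and 160.2 CPM over the other cells of the A/A TNF library. Of the sex-linked transcripts, 3 could be compared in A/A (median 0.86). The nuclear RNA Malat1, at 212, 991, 2096 and 5549.6 CPM in Kupffer-like cells against 16195, 20371, 17026 and 16278 in T cell-like cells, was lower in the macrophage class in all 4 libraries. Within Kupffer-like cells it was higher after TNF in both genotypes, and higher in S/S than in A/A at both times. Each comparison of this class can therefore also hold a difference in nuclear RNA. Whether its barcodes held whole cells was not tested. Genes with over 100 kb of intron had a median log2 ratio 0.33 (A/A) and 1.29 (S/S) above genes with under 1 kb in this class, but -2.61 to -1.95 and -2.34 to -1.48 from them in 6 other immune classes and -0.80 and -0.23 in mature DC-like cells.

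**Figure D3:**
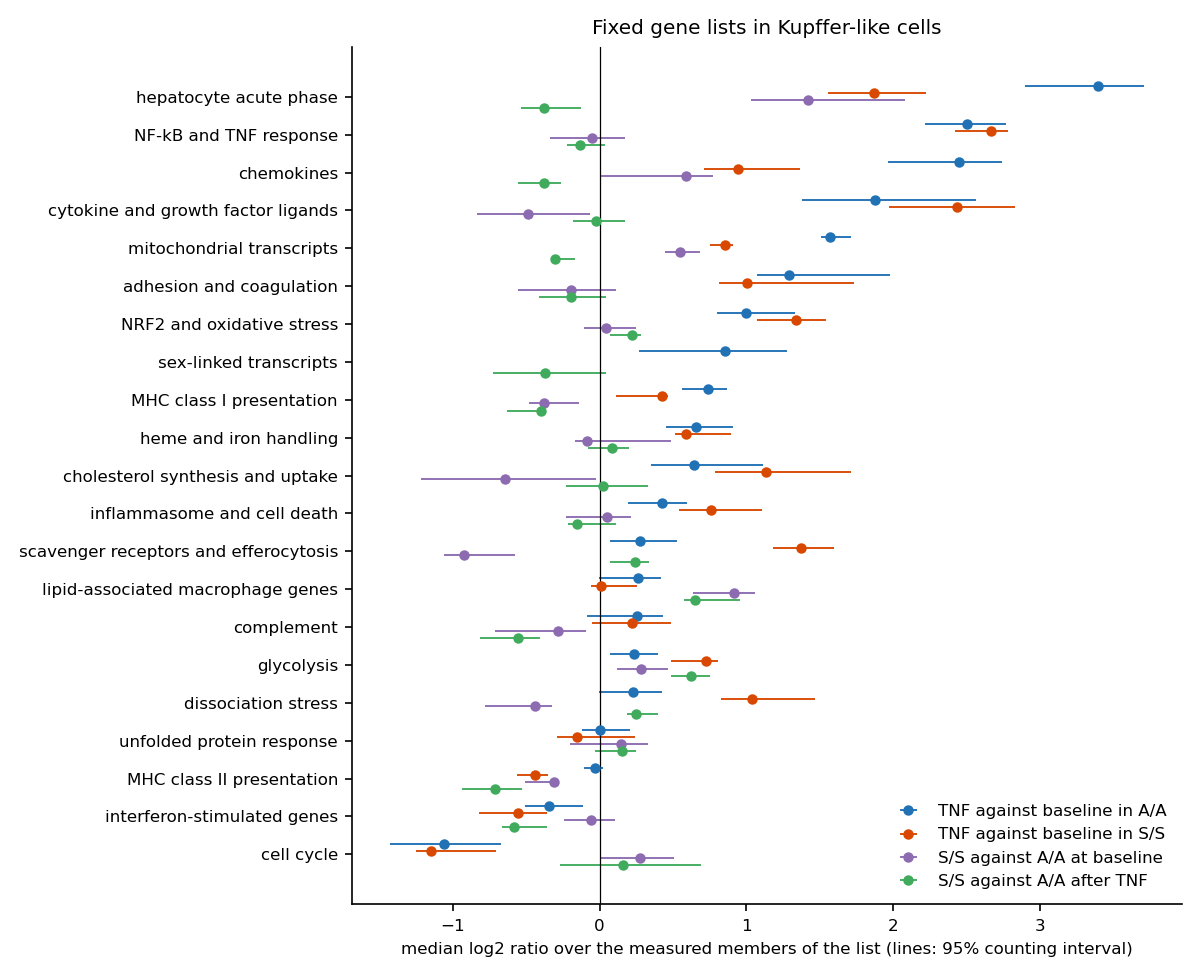
Median log2 ratio of each fixed gene list in Kupffer-like cells for the 4 comparisons, with lines for the 95% counting interval. The NF-kB and TNF response list stood at 2.51 and 2.67 for TNF, and the lipid-associated macrophage list at 0.92 and 0.65 for S/S against A/A.

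Whether the response to TNF differed with genotype was described by the S/S log2 ratio minus the A/A log2 ratio of each gene in Kupffer-like cells, in which a gene-specific factor cancels out only where it acted alike in both genotypes. The intron gap, at 0.33 in A/A and 1.29 in S/S, did not cancel, so the shifts of genes and lists can hold a part of it. The difference was not tested. Over 4634 genes its median was 0.067, and the NF-kB list had a median difference of 0.32, with 20 of 38 members larger in S/S. Scavenger receptor genes were shifted toward S/S by 0.70, with 16 of 20 members larger, as were dissociation stress genes by 0.62 and cholesterol genes by 0.51. Acute phase genes (-1.4995), mitochondrial transcripts (-0.85), MHC class I (-0.37) and class II genes (-0.36) and chemokines (-0.31) had larger TNF ratios in A/A, and the remaining lists had median differences from -0.26 to 0.28. Among single genes, the heat-shock genes Hspa1a and Hspa1b, which share near-identical sequence, were lower after TNF in A/A (-2.19 and -1.72) and higher in S/S (2.65 and 3.96 [2.55 to 7.54], the last from 2 UMIs at baseline). This was not limited to Kupffer-like cells, since both genes had the same directions in monocyte or macrophage-like, T cell-like, pDC-like and mature DC-like cells. The pancreatic enzymes of 1 A/A barcode and the Ftl1 pseudogenes also ranked among the largest differences.

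The effect of genotype was read from S/S against A/A Kupffer-like cells, first at baseline. Genes of lipid-associated macrophages, a state known from fatty and injured tissue, were higher in S/S: 14 of 18 list members were higher and 9 over 2-fold higher, with a median log2 ratio of 0.92 [0.64 to 1.06] at percentile 100. Fabp5 (ENSMUSG00000027533.11), a fatty acid-binding protein, was 8.26-fold higher (290.4 against 34.3 CPM), Cd63 (ENSMUSG00000025351.15), a lysosomal tetraspanin, 5.99-fold higher, and Trem2 (ENSMUSG00000023992.15), a lipid-sensing receptor, 4.45-fold higher. Gpnmb (ENSMUSG00000029816.11), a lysosomal glycoprotein, had 1 UMI in A/A and 36 in S/S (4.38 [2.79 to 10.71]); it and Trem2 are also on the marker list of monocyte or macrophage-like cells. Il1b (ENSMUSG00000027398.14), an inflammatory cytokine, was lower in S/S, at 67.3 against 528 CPM, as were Cxcl13 (log2 ratio -3.85) and C4b (ENSMUSG00000073418.5), a complement component (-2.86). The class was not made up alike: most A/A cells lay in cluster 22 (262 of 405) and most S/S cells in cluster 4 (466 of 525), where the Kupffer cell lectin Clec4f stood at 2808 and 328 CPM. Over all kept cells Clec4f stood at 128, 27.03, 53.8 and 20.2 CPM and Vsig4, another marker, at 81.4, 24.1, 26.3 and 17.7 CPM, so a difference in cell make-up between the genotypes was not excluded.

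Other genes higher in S/S at baseline were Cd209f (3.63 [3.16 to 4.21]), Cd209g (2.47 [1.93 to 3.12]), Ms4a7, a membrane protein of macrophages (2.44 [1.93 to 3.05]), Cela1, an elastase (2.26 [1.91 to 2.64]), and Ethe1, a mitochondrial sulfur dioxygenase (1.81 [1.25 to 2.46]). With barcodes holding a UMI of Clec4f, Timd4 or Vsig4 alone, the ratio of Cd209g was -0.016. Ftl1, the ferritin light chain, was higher in S/S (2.76) while its pseudogenes Ftl1-ps1, Ftl1-ps2 and Ftl2-ps were lower, and the sum of these 4 near-identical genes had a log2 ratio of 0.94, so the single values are uncertain. Gbp2b, an interferon-inducible GTPase, had 114 UMIs in A/A and 2 in S/S (-5.12 [-8.70 to -3.75]), and Dusp3, a phosphatase, was at -2.38 [-3.13 to -1.78]. Median depth was 2129 UMIs in A/A and 1362 in S/S, Rn18s-rs5 took 22.8% and 10.3% of the UMIs, and genes with over 100 kb of intron lay -1.28 from genes with under 1 kb.

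Scavenger receptors and efferocytosis genes were lower in S/S at baseline, with a median of -0.93 [-1.06 to -0.58] at percentile 0 and 9 of 19 over 2-fold lower, such as the receptor Axl (-1.64) and its ligand Pros1 (-1.45). The random lists behind that percentile were matched on expression and did not hold intron length fixed. MHC class II genes had a median of -0.31 with 0 of 10 members higher (Cd74 -0.66, H2-Ab1 -0.60), and MHC class I genes -0.38, with the peptide trimmer Erap1 at -2.06 and Tapbp at -1.19. Complement genes stood at -0.28, with 5 of 16 over 2-fold lower (C3 -2.04), and dissociation stress genes at -0.44, with Egr1 at -2.4998 and Dusp1 at -1.68. The heme and iron handling list had a median of -0.083 [-0.17 to 0.49] at percentile 12.2, with 11 of 22 members higher. Spic, a transcription factor of iron-recycling macrophages, was at 1.76 [1.40 to 2.16] and Hmox1 at 1.07. With cluster 4 alone the heme median was 0.67, and with genes of under 10 kb of intron alone 1.37. Acute phase genes were higher in S/S (1.42), such as Saa1 (2.73), although Saa1 was at 77.4 CPM in this class and 173 CPM over the other cells, and chemokines stood at 0.59, with Ccl5 at 2.48 and Ccl24 at -2.22. Leaving out genes more abundant in other cells turned the chemokine median to -0.41.

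Remaining lists at baseline had medians of -0.052 (NF-kB and TNF response, 7 over 2-fold higher and 6 over 2-fold lower of 30), -0.060 (interferon-stimulated genes, with Usp18 at 1.77) and 0.042 (NRF2 and oxidative stress). Inflammasome and cell death genes stood at 0.049, with Nlrp3 at -1.63, adhesion and coagulation genes at -0.20, and cytokine and growth factor ligands at -0.49, with Il18 at 1.09 and the interleukin 1 antagonist Il1rn at -1.40. Glycolysis had a median of 0.28, with Gapdh at 0.94 and the hexokinase Hk1 at -1.74, cholesterol synthesis and uptake -0.64 over 5 genes, cell cycle 0.28, unfolded protein response 0.14 and mitochondrial transcripts 0.55. Sex-linked transcripts had too few members for a median at baseline, with Ddx3y at -1.19 (0.43 with cluster 4 alone).

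After TNF, the lipid-associated macrophage list was again higher in S/S than in A/A Kupffer-like cells, with a median of 0.65 [0.58 to 0.95] at percentile 100, 14 of 17 members higher and 7 over 2-fold higher. Trem2 was 5.20-fold, Fabp5 5.02-fold and Cd63 4.32-fold higher, and Gpnmb, with no UMI in A/A, at least 21.5-fold higher. Ddit4 (ENSMUSG00000020108.5), an inhibitor of mTORC1 induced by hypoxia and stress, was 10.5-fold higher (with 35.8% of its UMIs in 1 barcode). The stress genes Gdf15 (2.73 [2.30 to 3.29]), Atf3 (2.11 [1.63 to 2.71]) and Klf4 (2.003 [1.41 to 2.80]) were also higher. MHC class II genes were lower in S/S, with 1 of 11 members higher and a median of -0.71 [-0.94 to -0.53], and the chemokine Cxcl13 was at 178 against 2058 CPM.

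Other genes higher in S/S after TNF were Ccr3, a receptor for eotaxins (2.22 [1.64 to 3.01]), H2bc4, a histone (2.34 [1.76 to 3.14]), and Atp13a2, a lysosomal polyamine transporter (2.05 [1.46 to 2.84]). Interferon-stimulated genes had a median of -0.58 [-0.66 to -0.36] at percentile 0, with 10 of 33 higher (Cxcl9 -1.78, Gbp3 -1.28, against Ifi27l2a at 1.64). Within the MHC lists H2-Ab1 stood at -1.16, H2-Aa at -1.09, and MHC class I genes at -0.40, with H2-Q7 at -1.74 and the peptide transporter subunit Tap2 at -1.16. Complement genes had a median of -0.56 [-0.82 to -0.40], with 6 of 17 over 2-fold lower (C4b -2.002, and C2 -2.71 [-5.52 to -1.502] with 3 UMIs in S/S). Glycolysis had a median of 0.62 [0.49 to 0.75] at percentile 100, with 14 of 18 higher, such as the enolase Eno1 (1.43) and the lactate exporter Slc16a3 (1.45), the last at -0.10 in cells thinned to equal depth. Scavenger receptors stood at 0.24, opposite in sign to baseline, but at -0.069 in thinned cells and -0.22 with each cell weighted equally.

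Heme and iron handling genes had a median of 0.087 [-0.081 to 0.20] after TNF at percentile 83.02, with 16 of 27 higher, including the ferrochelatase Fech (1.60) against Hamp, the iron hormone hepcidin (-0.87). Red cell RNA in this class also went with genotype, with Hba-a1 at 14.7, 1545, 191 and 1677 CPM, so heme genes that red cells express are uncertain here. NRF2 genes stood at 0.22 (Slc7a11 1.72, Nfe2l2 -0.85), dissociation stress genes at 0.25, and chemokines at -0.38 (Ccl22 -1.89). The NF-kB and TNF response list was at -0.13 [-0.22 to 0.040], with 6 of 38 members over 2-fold higher, such as Ccl7 (1.68), and 1 over 2-fold lower. Inflammasome and cell death genes (-0.16), adhesion and coagulation genes (-0.19), cytokine ligands (-0.023), cholesterol genes (0.021), cell cycle genes (0.16), unfolded protein response genes (0.15), acute phase genes (-0.38), mitochondrial transcripts (-0.30) and 3 sex-linked transcripts (-0.37) completed the lists. Within them, Il23a, a subunit of interleukin 23, had 1 UMI in A/A and 26 in S/S (3.65 [2.38 to 10.34]), the growth factor Igf1 was at 1.20, and Procr, a coagulation receptor, at -2.04. The lowest genes after TNF were the pancreatic enzymes that 1 A/A barcode held. Kupffer-like cells came mostly from cluster 15 in A/A and from cluster 4 in S/S.

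Genes higher in S/S at both times, by the smaller of the ratios, were Fabp5, Cd63, Trem2, H2bc4 (1.59 and 2.34), Clec4a2, an inhibitory lectin (1.19 and 1.45), Prxl2b (1.21 and 1.44) and Lgals3 (ENSMUSG00000050335.18), the galectin of activated macrophages (1.17 and 1.21, with CPM of 434, 977, 440.3 and 1018). Genes lower in S/S at both times included Cxcl13 (-3.85 and -3.52), C4b (-2.86 and -2.002), the chemokines Cxcl9 (-1.84 and -1.78) and Ccl24 (-2.22 and -0.95), and the apolipoprotein Apoc1 (-1.40 and -0.93). Across the same 4634 genes the genotype ratios at baseline and after TNF had a Pearson correlation of 0.28 and a Spearman correlation of 0.34, with the same sign in 62.6% of the genes.

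**Figure D4:**
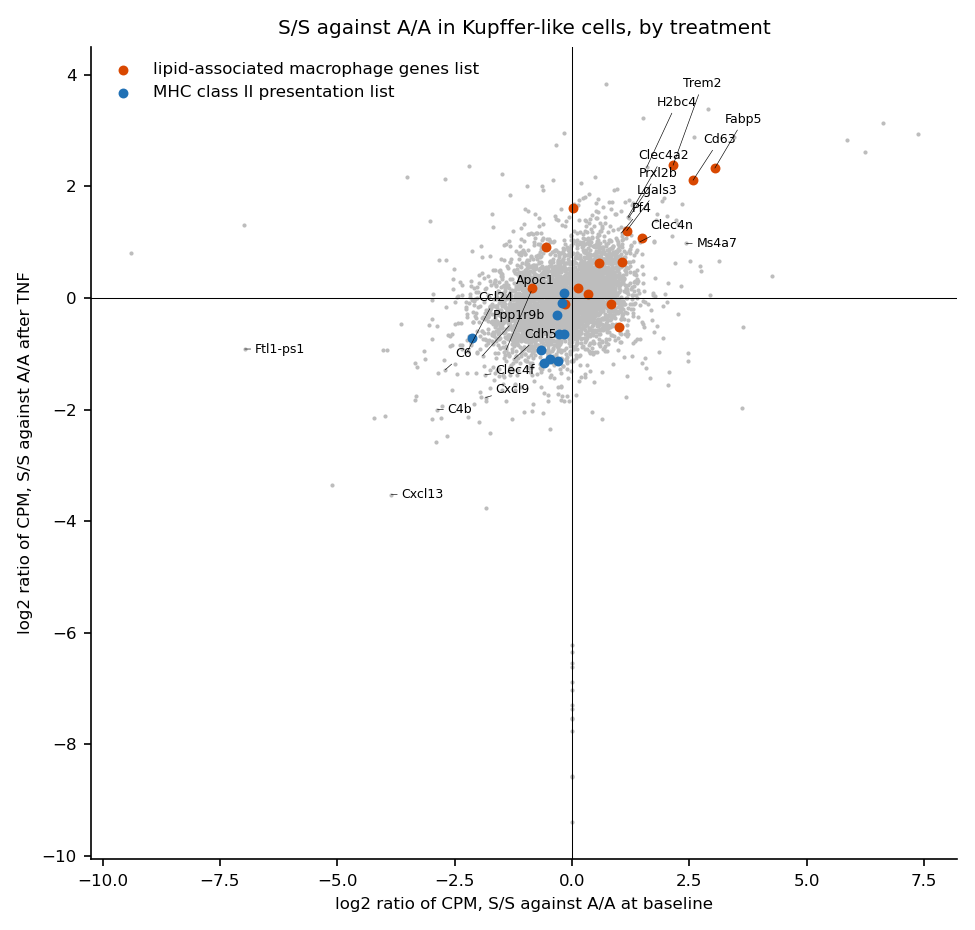
Log2 ratio of CPM for S/S against A/A at baseline (x axis) and after TNF (y axis), with 1 point per gene in Kupffer-like cells and genes of the lipid-associated macrophage and MHC class II lists in colour. Fabp5 (3.05 and 2.33) and Trem2 (2.16 and 2.38) lay in the upper right and Cxcl13 (-3.85 and -3.52) in the lower left.

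Other cell classes were compared the same way to see which liver cells differed after TNF. Of these classes, hepatocyte-like and endothelial-like cells had the highest NF-kB medians: 3.13 in A/A and 2.78 in S/S hepatocyte-like cells, and 2.64 in A/A endothelial-like cells. Neutrophil-like cells stood at 2.42 and 2.36, monocyte or macrophage-like cells at 1.46 and 1.90, and B cell-like cells lowest at 0.57 and 0.39. In A/A endothelial-like cells Ch25h, which makes an oxysterol, was at least 117-fold higher, Cxcl11, a T cell-attracting chemokine, at least 79.03-fold higher, and Ccl2 went from 3 to 8645 UMIs (8.46 [7.22 to 11.05]). Hepatocyte-like cells had more Mt1 in A/A (8.65 [8.28 to 9.10]) and more Serpina1e in S/S (6.998 [6.22 to 8.06]) after TNF, and neutrophil-like cells more Cxcl2 in A/A (6.88 [6.44 to 7.42]).

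Monocyte or macrophage-like cells had more Slpi, a protease inhibitor, in A/A (6.58 [6.09 to 7.26]) and Sdc4 in S/S (4.96 [4.76 to 5.25]) after TNF. Interferon-stimulated genes were lower in them: 40 and 37 of 44 were over 2-fold lower, with medians of -2.21 and -2.05. Their MHC class II medians were -1.82 and -1.02, and Trem1, an amplifier of inflammation, was at least 48.8-fold higher in A/A. Interferon-stimulated genes were also lower in pDC-like (-0.97 and -1.56) and neutrophil-like cells (-0.70 and -1.27), but higher in A/A hepatocyte-like (1.73) and endothelial-like cells (1.20). NK or ILC1-like cells had NF-kB medians of 1.41 and 1.33, with the protease inhibitor Serpina3f at 3.94 [3.30 to 5.02] and 3.21 [2.78 to 3.84]. T cell-like cells had 1.06 and 1.23, with Serpina3g at 2.96 [2.82 to 3.16] in A/A. The NK or ILC1-like class was mixed at baseline. There cluster 24, with 9 NK or ILC1 and 9 T cell markers, held 91 of 140 A/A and 159 of 307 S/S cells. After TNF nearly all lay in cluster 14, with 10 and 2 such markers, so the TNF ratios of this class can also compare kinds of cells. In pDC-like cells the NF-kB list stood at 1.14 and 1.44 and Adgrg5, an adhesion receptor, at 4.16 [3.55 to 6.83] and 3.26 [2.67 to 4.52], and in mature DC-like cells the list stood at 0.81 and 1.16. This last class was mixed: its cluster had 8 mature DC and 7 cDC1 (conventional dendritic cell) markers, and at Leiden resolution 2 only 14 and 7 baseline cells kept the name, beside 70 and 51 cDC1-like cells, so its TNF ratios also compare kinds of dendritic cells. Leaving out genes more abundant in other cells turned the NF-kB median to -0.62 and -0.73 in B cell-like, -0.94 and -0.45 in pDC-like, -0.15 and -0.079 in mature DC-like, and, in S/S, -0.13 in T cell-like and -0.070 in NK or ILC1-like cells. Erythroid-like cells could be compared in S/S alone, with an NF-kB median of 1.03. Cells of the TNF and baseline libraries lay mostly in different clusters in the monocyte or macrophage-like (7 and 20), T cell-like (5 and 8), B cell-like (13 and 2), NK or ILC1-like (14 and 24), neutrophil-like (0 and 23) and pDC-like classes (18 and 19). In A/A this also held for endothelial-like (10 and 21) and hepatocyte-like cells (3 and 16). Endothelial-like values after TNF in A/A came from 372 cells and left out unnamed cluster 1, with 14 endothelial markers and 1168 cells of that library. Its depth was 0.28 of the library median, close to the 0.27 of the named baseline cluster 21, so these TNF ratios compare unlike parts of the endothelial-marker barcodes. Median depth was 1337.5 UMIs at baseline and 12092.5 after TNF in A/A endothelial-like cells, and 3378 and 19119 in S/S mature DC-like cells. Across genes the A/A and S/S TNF ratios had Pearson correlations from 0.47 in mature DC-like to 0.86 in pDC-like cells.

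**Figure D5:**
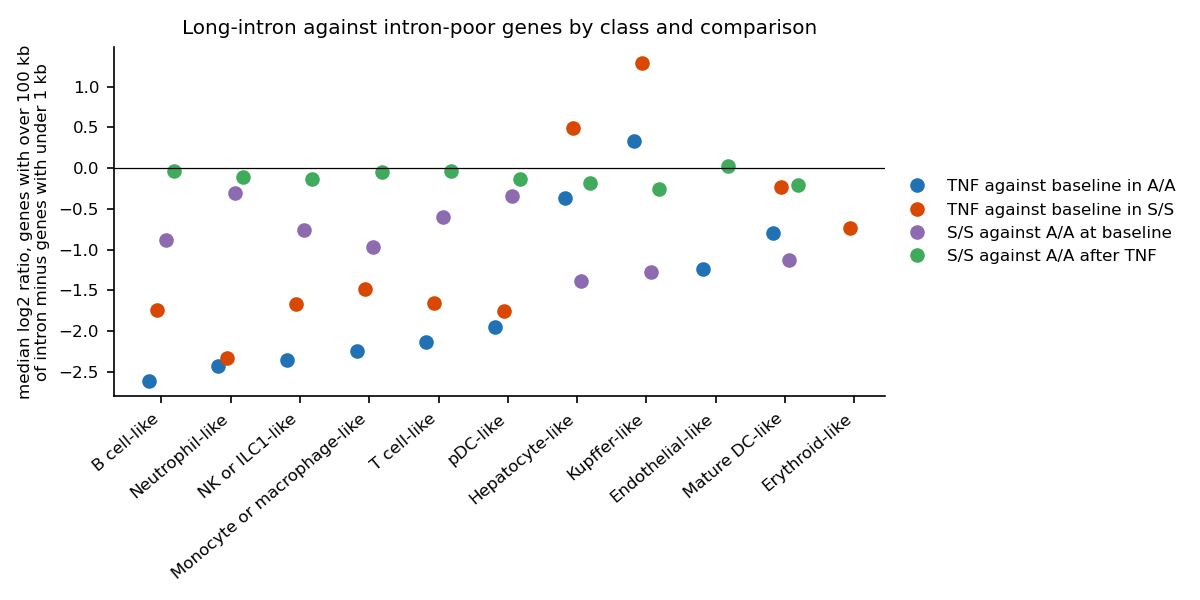
Median log2 ratio of genes with over 100 kb of intron minus that of genes with under 1 kb, with 1 point per cell class and comparison. In S/S against A/A after TNF, between libraries of 1 software version, the gap was at most 0.26 in size, and in TNF against baseline it ran down to -2.61.

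Genotype differences in the other classes were read within the baseline and within the TNF libraries. Glycolysis medians were above 0 in S/S in all compared classes at both times, highest in monocyte or macrophage-like cells at baseline (1.07, with 16 of 18 higher), and in endothelial-like cells after TNF (1.25, with 16 of 17 higher). After TNF, monocyte or macrophage-like cells of S/S had more Egln3, an oxygen-sensing hydroxylase (2.97 [2.73 to 3.62]), Mxi1, an antagonist of MYC (2.89 [2.63 to 3.80]), and Hilpda, a lipid droplet protein (2.19 [1.97 to 2.58]). Neutrophil-like cells of S/S had more Egln3 (2.77 [2.61 to 3.02]) and Cxcl3 (2.92 [2.76 to 3.19]). In monocyte or macrophage-like cells, Egln3 (0 UMIs in A/A and 104 in S/S) and Hilpda (2.77 [1.72 to 5.02]) were already higher in S/S at baseline. Mxi1 in that class stood at 50.1, 47.2, 3.79 and 34.5 CPM over the 4 libraries, so it was lower after TNF in both genotypes, and more so in A/A. S/S endothelial-like cells had more Pgf, placental growth factor (5.18 [4.86 to 7.46]), and less Tnfsf10 (-2.95 [-3.41 to -2.66]), Icosl (-2.58 [-3.14 to -2.23]) and Cxcl13 (-3.83 [-4.59 to -3.46]) after TNF. Their interferon-stimulated genes had a median of -0.73. The endothelial-like values leave out unnamed cluster 1, with 1168 A/A and 447 S/S cells after TNF. At baseline, hepatocyte-like cells of S/S had more Mt1 (5.58 [5.20 to 6.04]) and Lcn2, a siderophore-binding acute phase protein (4.81 [4.36 to 5.38]), and less Mup7 (-4.90 [-5.83 to -4.19]). They came mostly from cluster 3 in S/S and cluster 16 in A/A. Lcn2 is also on the neutrophil marker list. In these A/A and S/S barcodes the neutrophil gene S100a8 stood at 12.6 and 819 CPM and Hba-a1 at 22.1 and 3022 CPM, so RNA from other cells was not excluded.

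Cell cycle genes were higher in S/S T cell-like cells, with medians of 1.29 at baseline and 1.58 after TNF, when 22 of 22 were higher. The checkpoint receptor Pdcd1 was at 2.79 [2.59 to 3.22] and Art2a, an ADP-ribosyltransferase, at -2.18 [-2.44 to -1.97]. Of the 470, 872, 897 and 306 T cell-like cells, cluster 11, with Cd8a and Pdcd1 in the lead, held 56, 328, 177 and 86, a larger share in S/S at both times. Cluster 25, led by cell cycle genes such as Top2a, held 43, 83, 33 and 43, a larger share in S/S after TNF but a close one at baseline. Interferon-stimulated genes were higher in S/S pDC-like cells at baseline (0.92, with 38 of 41 higher) and lower in S/S NK or ILC1-like cells after TNF (-0.48). In the latter, Gzmc, a granzyme, was at -3.59 [-4.71 to -2.84] and the integrin Itga1 at -2.66 [-3.52 to -2.02]. B cell-like cells of S/S had more Id3, an inhibitor of DNA binding (1.89 [1.68 to 2.15]), and less Cxcr4, a homing receptor (-1.87 [-2.03 to -1.74]), at baseline. After TNF they had less Cxcl13 (-2.85 [-3.57 to -2.33], with 36% and 33.2% of its UMIs in 1 barcode). Mature DC-like cells of S/S had more Il12b (2.38 [2.03 to 2.89]) and less Apol7c (-2.33 [-2.51 to -2.18]) after TNF. Endothelial-like cells were not compared at baseline, where the S/S library held 36 of them. Genotype ratios at both times correlated less across genes than TNF ratios did, with Pearson correlations from 0.14 in mature DC-like to 0.46 in T cell-like cells. The TNF comparisons also share a difference in software version, and the genotype comparisons do not. Their correlations therefore do not show which effect was more alike.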

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

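The tests of intron counting and of a response of long genes, of reads split with Ftl1 pseudogenes and of genotype for Ftl1, and of cluster shares, ribosomal RNA and intron reads for the lipid-associated macrophage list were chosen only after the result was seen. The tests of low-quality barcodes, of a general difference in read assignment, of another macrophage type and of RNA from other cells were written before it. The limits under which those of low-quality barcodes, of another macrophage type and of RNA from other cells were read as undecided were set after it.

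In Kupffer-like cells, 5 genes drew attention because their TNF ratios lay on opposite sides of 0 in the genotypes, each with a counting interval clear of 0. Only genes already named by size were searched, among them those with the largest differences, and both ratios had to be at least 1 in size. Opposite signs as such were common, since 76.7% of 4634 genes had the same sign. The difference was not tested, since each group held 1 library. Given as the S/S log2 ratio minus the A/A log2 ratio, the 5 genes were Ccl5 (-3.47), Ccr3 (3.71), Ftl1-ps1 (6.05), Hspa1a (4.84) and Hspa1b (5.68). Ccl5, a chemokine that T cells also make, stood at 45.1, 256, 216 and 108 CPM over the 4 libraries, and Ccr3 at 64.7, 22.4, 14.5 and 71.6 CPM. Hspa1a and Hspa1b are near-identical copies that share reads. Their opposite signs were not limited to this class: Hspa1b stood at -3.04 [-3.91 to -2.66] in A/A and 1.12 [0.56 to 2.09] in S/S monocyte or macrophage-like cells, and over the 4 libraries at 4.09, 0.418, 0.479 and 33.7 CPM in T cell-like, 7.70, 0, 1.81 and 90.1 CPM in pDC-like and 68.6, 0, 1.31 and 44.8 CPM in mature DC-like cells. An effect of handling on them was not tested. A further signal lay in barcodes that the filter removed and that no comparison used: globin genes held 37.4% of their UMIs in the S/S baseline, 38.1% in the A/A TNF and 50.7% in the S/S TNF library, against 3.63% in the A/A baseline library. These barcodes numbered 400, 617, 79 and 320, and the TNF matrices had already been filtered before deposit.

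The first pattern was a gap between genes with over 100 kb and under 1 kb of intron in TNF against baseline, from -2.61 to -1.95 over 6 immune classes in A/A, but -0.80 in mature DC-like cells and of the opposite sign in Kupffer-like cells. Low-quality barcodes at baseline stayed undecided beyond A/A T cell-like cells. There a stricter filter left the gap at -2.12 against -2.13, so barcodes outside its limits did not make the gap in that class. It removed few of them, with 451 against 470 cells at baseline and 864 against 897 after TNF. Other classes and other measures of quality were not tested. Between the TNF libraries the gap was at most 0.26 in size, but between the baseline libraries, also of 1 software version, it reached 1.39. Counting of introns at baseline alone is a candidate explanation that stayed undecided, with a Spearman correlation of -0.45 across 10 classes between the gap and Malat1, a nuclear RNA. A response of long genes to TNF was looked for as a gap more negative in classes with a larger NF-kB median. The correlation between them was 0.48, of the opposite sign, so a response that grew with that median was not seen. A response of another form cannot be told apart from intron counting, because TNF and software version separate the same libraries.

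The second pattern was that Ftl1 was low and its 3 pseudogenes were high in the A/A baseline library, with 1.86 to 2.55 pseudogene UMIs per Ftl1 UMI over 9 classes. A general difference in read assignment was argued against, since 1.23% of 162 other pseudogenes (2 genes) lay beyond a log2 ratio of 2, and so was genotype, since no class of the A/A TNF library held more than the 0.0211 pseudogene UMIs per Ftl1 UMI of its Kupffer-like cells. Reads of Ftl1 split with its pseudogenes in that library may explain the pattern: the highest ratio was 1.37 times the lowest, as 1 source of reads would give. Why 1 library alone showed it stays open.

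The third pattern was the higher lipid-associated macrophage list in S/S Kupffer-like cells at both times. Cluster shares, ribosomal RNA and intron reads were argued against as the whole cause. The median at baseline was 0.92 in cluster 4 alone and 0.71 without ribosomal RNA in the totals. It lay at percentile 100 of random lists matched on expression and intron length (after TNF 1.04, 0.62 and 100). RNA from other cells stayed undecided, with a median of 1.03 without genes more abundant in other cells (0.91 after TNF). That choice kept genes by their level in the library where they were higher. It cannot exclude RNA shared by all droplets of a library. Cells of another macrophage type stayed open, also within cluster 4, where Cd5l stood at 307 and 1863, Marco at 182 and 1469 and the monocyte gene Ccr2 at 269 and 78.1 CPM in A/A and S/S at baseline. The median was 0.74 (0.72 after TNF) among barcodes with a UMI of Clec4f, Timd4 or Vsig4, but such barcodes were 344 of 405 in A/A and 244 of 525 in S/S at baseline, 16.4% and 9.90% of lymphocyte-like barcodes also held one, and Clec4f in the Kupffer-like barcodes chosen stood at 2438 and 1168 CPM, so the choice did not hold the cell type fixed. Other classes had medians of 0.36 to 0.93 over 8 classes at baseline and, over 9 after TNF, of 0.001 [-0.042 to 0.13] in neutrophil-like to 0.97 in T cell-like cells. A difference between the genotypes may lie behind the pattern but stays a hypothesis. A difference in macrophage make-up or one across the whole library stands beside it, since mice, sort and library went with genotype in a single library each.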

How the results depend on the processing

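The alternatives that removed the highest doublet scores, left ribosomal RNA out of the totals, took cluster 4 or barcodes with a UMI of Clec4f, Timd4 or Vsig4 alone, used list genes of under 10 kb of intron or summed Ftl1 with its pseudogenes were chosen only after the data were seen. Each result was recomputed with 1 setting altered (both limits in the filter, and thinning also left out shallower cells). Each value was set against the 95% counting interval of the value reported above, and a sign counted as reversed only where that interval was clear of 0. A gene also needed a log2 ratio of at least 1 in size, and a list a percentile outside the middle 95%. Other changes of sign were counted only as inside or outside the interval. Of 4981 values of named genes, 4276 stayed within the interval, 693 lay outside it and 12 reversed. For lists in Kupffer-like cells these numbers were 959, 243 and 5 of 1207, and for lists in other classes 946, 363 and 19 of 1328. Of 312 shares 90 lay outside their interval, as did 18 of 26 correlations. Of 56 counts of genes shared with the 10 highest and 10 lowest, 36 stayed close to the full number and 20 did not, with 2 genes shared for genotype after TNF in thinned cells. With predicted doublets kept or with median-of-ratios size factors, no sign reversed and the correlations, the NF-kB and heme medians and the Kupffer-like shares (shares for doublets alone) stayed within their intervals. The NF-kB medians ran from 2.04 to 2.85 in A/A and 2.06 to 2.81 in S/S, their untested difference from 0.002 to 0.48, and the heme medians from -0.29 to 1.37 at baseline and -0.18 to 0.17 after TNF, on both sides of 0.

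With at least 500 genes and at most 10% mitochondrial UMIs per cell, the Pearson correlations were 0.75 for TNF and 0.36 for genotype, and the Kupffer-like shares were 6.79% (A/A TNF), 5.86% (S/S TNF) and 8.04% (S/S baseline). With listed genes left among the variable genes, the Pearson correlations were 0.76 for TNF and 0.35 for genotype, and the Kupffer-like share was 9.46% (A/A TNF). Signs reversed here for the interferon list in neutrophil-like cells (-0.10 for genotype at baseline). At Leiden resolution 2, the Pearson correlation was 0.73 for TNF, and the Kupffer-like shares were 11.6% (A/A baseline), 5.499% (S/S TNF) and 6.12% (S/S baseline). The sign was opposite for Spp1 (0.29) for TNF in S/S. In cells thinned to 1000 UMIs, the Pearson correlations were 0.78 for TNF and 0.42 for genotype. Under this choice signs reversed for Sel1l (-0.26) and Srebf2 (-0.35) for TNF in S/S, Slc16a3 (-0.10) for genotype after TNF, the NF-kB list in B cell-like cells (-0.21 for TNF in S/S), the chemokine list in monocyte or macrophage-like cells (-0.66 for TNF in A/A) and NK or ILC1-like cells (0.11 for genotype after TNF), and the scavenger receptor list in Kupffer-like cells (-0.069 for genotype after TNF). With the mean of each cell's CPM, the Pearson correlations were 0.68 for TNF and 0.31 for genotype, and the NF-kB median 2.07 (TNF in A/A) and the heme median -0.18 (genotype after TNF). Sign reversals were seen for the scavenger receptor list in Kupffer-like cells (-0.22 for genotype after TNF). At a pseudocount of 10 CPM, the Pearson correlations were 0.74 for TNF and 0.32 for genotype, and the NF-kB median 2.04 (TNF in A/A) and the NF-kB median 2.06 (TNF in S/S). Removing the highest doublet scores, the Pearson correlation was 0.72 for TNF, and the Kupffer-like shares were 15.8% (A/A baseline) and 13.1% (S/S baseline). Signs reversed here for the chemokine list in NK or ILC1-like cells (0.10 for genotype after TNF). In cluster 4 alone, the Pearson correlations were 0.59 for TNF and 0.14 for genotype, and the NF-kB median 2.13 (TNF in S/S) and the heme median 0.67 (genotype at baseline). The sign was opposite for Anxa1 (-0.40), Cd93 (-1.35) and Tap2 (-1.11) for TNF in A/A, C6 (0.11) for genotype after TNF, Ddx3y (0.43) and Gclc (0.27) for genotype at baseline, Tap1 (-0.17) for TNF in S/S, and the MHC class I list in Kupffer-like cells (-0.12 for TNF in A/A). In barcodes with a UMI of Clec4f, Timd4 or Vsig4, the Pearson correlation was 0.74 for TNF. Under this choice signs reversed for Cd209g (-0.016) for genotype at baseline. With genes of at least 500 UMIs, the Pearson correlations were 0.80 for TNF and 0.37 for genotype. Without ribosomal RNA in the totals, the Pearson correlation was 0.27 for genotype, and the NF-kB median 2.80 (TNF in S/S) and the heme median -0.29 (genotype at baseline). With list genes of under 10 kb of intron, the NF-kB median was 2.85 (TNF in A/A) and the heme median 1.37 (genotype at baseline). Leaving out genes more abundant in other cells, the NF-kB median was 2.81 (TNF in S/S), over 13 members against 38. Sign reversals were seen for the NF-kB list in B cell-like cells (-0.62 for TNF in A/A, -0.73 for TNF in S/S), mature DC-like cells (-0.15 for TNF in A/A, -0.079 for TNF in S/S), NK or ILC1-like cells (-0.070 for TNF in S/S), T cell-like cells (-0.13 for TNF in S/S) and pDC-like cells (-0.94 for TNF in A/A, -0.45 for TNF in S/S), the chemokine list in Kupffer-like cells (-0.41 for genotype at baseline), monocyte or macrophage-like cells (-1.34 for TNF in A/A, -0.64 for TNF in S/S) and T cell-like cells (-0.13 for TNF in S/S), the glycolysis list in Kupffer-like cells (-0.034 for TNF in S/S), and the interferon list in NK or ILC1-like cells (-0.13 for genotype at baseline, 0.52 for TNF in S/S). With a minimum of 1 UMI, the sign reversed for the chemokine list in T cell-like cells (-0.12 for genotype at baseline). The cause of these differences was not tested. Depth limited what could be compared: 20 UMIs in a pair of libraries were required, Kupffer-like cells numbered 354, 373, 452 and 323 after thinning and 137, 466, 194 and 292 in cluster 4, and lists left with too few measured genes under an alternative had no value there. No paired analysis was possible because each group held 1 library of pooled mice, and a model of all 4 libraries without an interaction was not fitted.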

Other observations

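All genes and clusters in this part were chosen only after their values were seen, and no explanation was tested. Some single genes that low oxygen can induce were higher in some classes after TNF, in S/S against A/A, and others were not. Vegfa, a growth factor for vessels, had log2 ratios of 2.66 [2.30 to 3.35] in endothelial-like cells, 3.08 [2.90 to 4.88] in monocyte or macrophage-like cells and 2.79 [2.09 to 9.98] in mature DC-like cells, the last with 1 UMI in A/A, but 0.25 [-0.070 to 0.59] in neutrophil-like cells. Slc2a1, a glucose transporter, was higher in endothelial-like cells (3.17 [2.95 to 3.49]) but not in Kupffer-like cells (-0.33 [-0.91 to 0.21]). Bnip3, a mitophagy receptor, stood at 2.16 [1.95 to 2.44] in endothelial-like, 1.87 [1.73 to 2.06] in monocyte or macrophage-like and 1.94 [1.38 to 2.94] in mature DC-like cells, and Ankrd37 at 2.08 [1.58 to 3.22] in endothelial-like, 2.33 [1.26 to 4.40] in Kupffer-like and 1.60 [1.36 to 1.97] in neutrophil-like cells. Hilpda stood at -0.063 [-0.38 to 0.25] in Kupffer-like cells and Mxi1 at 0.16 [-0.14 to 0.46] in neutrophil-like and -0.18 [-1.68 to 1.08] in NK or ILC1-like cells, while Ndrg1 was at -0.33 [-0.52 to -0.15] in neutrophil-like and -0.53 [-1.18 to 0.066] in Kupffer-like cells. At baseline, monocyte or macrophage-like cells of S/S already had more Bnip3 (2.36 [1.69 to 3.35]), Slc2a1 (1.80 [1.25 to 2.52]) and Ankrd37 (3.85 [2.75 to 6.61], from 3 UMIs in A/A).

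Over all kept cells, transcripts of the red cell lineage followed the shares of erythroid-like cells. Alas2, the erythroid enzyme of heme synthesis, stood at 26.9, 215, 27.6 and 429 CPM in the A/A baseline, S/S baseline, A/A TNF and S/S TNF libraries, and Hba-a1, a globin that shares reads with its copy, at 1307, 15900, 2265 and 30080 CPM. Hmox1 over all kept cells was at 67.1, 197, 657 and 1238 CPM.

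Among the unnamed clusters, cluster 17 took 0 of the A/A baseline cells (upper limit 0.131%), 0.0229% of the S/S baseline cells, 1.13% [0.888 to 1.42] of the A/A TNF cells and 7.16% [6.497 to 7.88] of the S/S TNF cells. Its leading genes included macrophage genes such as Lpl, C1qb and Spic. The median of 15395.5 UMIs per barcode lay below the 21405 and 21128.5 of monocyte or macrophage-like cells in the A/A and S/S TNF libraries. Its best class was monocyte or macrophage, with 5 markers, among them Gpnmb and Trem2. It stayed unnamed because its leading genes held a marker of platelets, Pf4, so no comparison used it. Doublets were not excluded, since doublet removal did not work. Cluster 1, with Akap12, Fabp4, Gpihbp1 and Clec4g in the lead and a median of 1702.5 UMIs, took 0.142, 0.252, 18.1 and 8.09%. Cluster 26, with Ptgs2, Il36g and Il1b, was seen in the TNF libraries alone (2.17 and 1.09%, against upper limits of 0.131 and 0.0845% at baseline), and cluster 30, with Cd209a and Mgl2, in the baseline libraries alone (1.49 and 2.20%, against 0.0572 and 0.0667% after TNF). The other 5 unnamed clusters held 2, 125, 31 and 2 (cluster 28), 0, 1, 3 and 36 (32), 3, 31, 1 and 0 (34), 3, 16, 3 and 10 (35) and 0, 5, 2 and 18 cells (37). Whole-library Xist, from the inactive X chromosome, had 1, 3, 15 and 6 UMIs.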
